A study of Cochliomyia hominivorax with 18 samples.

How the data were processed

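Poly(A)-selected RNA from larval and adult midguts was sequenced in 18 libraries, per the labels' protocols, which name a column-based RNA isolation and NEBNext library kits. The deposited table holds raw counts per predicted transcript for all 18 libraries, judged from its whole numbers and from column sums that differ between libraries. Trimmomatic, STAR, featureCounts and DESeq2 are named in the submitters' processing notes without versions, roles or order. The genome build, the annotation, the strand setting and whether a read pair was counted as 1 or 2 are not given in the sources used here. Even values were over-represented among low counts: 63.0% to 71.3% of counts from 1 to 20 were even, against 50.7% to 54.4% of counts above 100. That is the pattern of pairs counted as 2 reads, and counts halved and rounded down were therefore tried as an alternative.

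Each column was matched to a sample by its name, and groups and replicate numbers were taken from the sample titles. All per-sample columns were used. Within groups, pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom 295 to 1387), so none was counted as a duplicate. No row was a total or an unassigned class. A total of 2274 transcripts belong to gene numbers with more than 1 listed transcript, and reads shared between such transcripts or between near-identical genes could have been split or lost in the authors' counting, so single members of such families are uncertain.

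The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Transcripts were kept by filterByExpr on the groups of each fit (minimum count 10, minimum total count 15), scaled by TMM, and tested with the quasi-likelihood F-test (glmQLFit, glmQLFTest). Benjamini-Hochberg adjustment ran over all transcripts tested, and an FDR under 0.05 without a fold threshold was called. The 6 treatment comparisons used the 9 libraries of a stage with a mean per group, so that the groups shared an estimate of spread. The comparison of control adults with control larvae and the interactions (treatment effect in adults minus that in larvae) used all 18 libraries. Standard errors and 95% intervals of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled. Log2 CPM for principal components and for correlations of changes used a prior count of 2. Floors use 3 counts per library, and floors and intervals on counts cover counting error only, since reads without molecular identifiers are not independent molecules.

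These tests, the groups in each fit, the naming rule and the alternatives listed first were chosen before the data were examined. The naming rule took, per comparison between 2 groups, transcripts past FDR 0.05 whose groups did not overlap in CPM, and since no names are paired with the IDs it kept at most 2 that rose and 2 that fell with the largest changes. Lists of genes for immunity, digestion, detoxification, mitochondria, the cell cycle and other tissues had been fixed by gene name. They could not be tested, because the table pairs no names with its IDs and a reference annotation was not used here.

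Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE size factors, library totals without scaling factors, no filter on low counts, a filter of 1 CPM in 3 libraries, an added log2 fold threshold of 1, the replicate number as a block, a digit (1 or 2) in the library name as a covariate, only the 6 libraries compared, all 18 libraries, and leaving out each library. After the data were seen, halved counts, transcripts summed per gene number, libraries thinned to equal totals, a covariate from the main axis of larval library differences, on-Tc against the other 6 libraries of a stage, and the correlation of larval with adult changes were added.

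Recovery was tested on simulated counts drawn from the libraries' means, totals and dispersions, with 200 transcripts changed 1.5, 2, 4 or 8-fold, in 3 simulations per comparison. The edgeR test found 30.0% of 4-fold and 62.0% of 8-fold changes for on-Tc against control in adults (11435 transcripts, 1.42% of calls false), and 46.0% and 68.7% for the stage comparison (12599 transcripts). For the on-Tc interaction it found 14.0% and 51.3%. DESeq2 found 63.3% and 82.0% in adults, with 37.1% of calls false and up to 31 calls where nothing had been changed. The false shares hold for 200 changed transcripts and do not carry over to real lists of other lengths. Shared-control values came from 10 simulations of unchanged groups, with each transcript drawn independently. Groups of 3 against 3 allow 10 splits, so an exact test cannot go below p = 0.1 (two-sided), while 3 against 6 allow 84. Figures were drawn with matplotlib 3.10.9.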

Results

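Midgut RNA was sequenced from larvae and adults of the New World screwworm, Cochliomyia hominivorax, a fly whose larvae feed on the living tissue of warm-blooded animals. Midguts of production flies were taken before, during and after rearing with tetracycline, an antibiotic that blocks protein synthesis in bacteria; it is also used to switch off conditional transgenes in insect strains, and the question was whether rearing with it has lasting effects on the gut. The 18 libraries form 6 groups of 3: control, on-Tc (during tetracycline) and post-Tc (after it) in each of the 2 stages. Library totals ran from 30221028 to 78052370 counts in larvae and from 19158409 to 79783813 in adults. The table lists 22420 predicted transcripts of 21161 gene numbers, of which 3722 had 0 counts in every library, and a library detected 12955 to 15260 of them. The deposited table gives IDs (a gene number and a transcript number) without gene names, so transcripts are reported by ID and no gene group could be described. The labels number the libraries of a group 1 to 3 without saying whether they came from separate animals or cages, so p-values measure only the spread between these libraries.

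Life stage separated the libraries far more than tetracycline did. The first principal component of log2 CPM held 60.5% of the variance and parted larvae from adults, while the second held 7.84%. Among the 9 larval libraries, 23.1% of the variance lay between the treatment groups, which did not stand out from other groupings in an exact test over 280 partitions (p = 0.614; median of the other partitions 24.5%). Among the 9 adult libraries the share was 33.2% (exact p = 0.0857; median of the others 23.7%). The first larval component, with 33.1% of larval variance, set control 2, post-Tc 1 and post-Tc 2 apart from the other 6 larval libraries, a split that crosses the treatment groups. In adults, the 10 most abundant transcripts took 13.9% to 31.8% of a library's counts, against 8.91% to 16.02% in larvae.

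**Figure D1:**
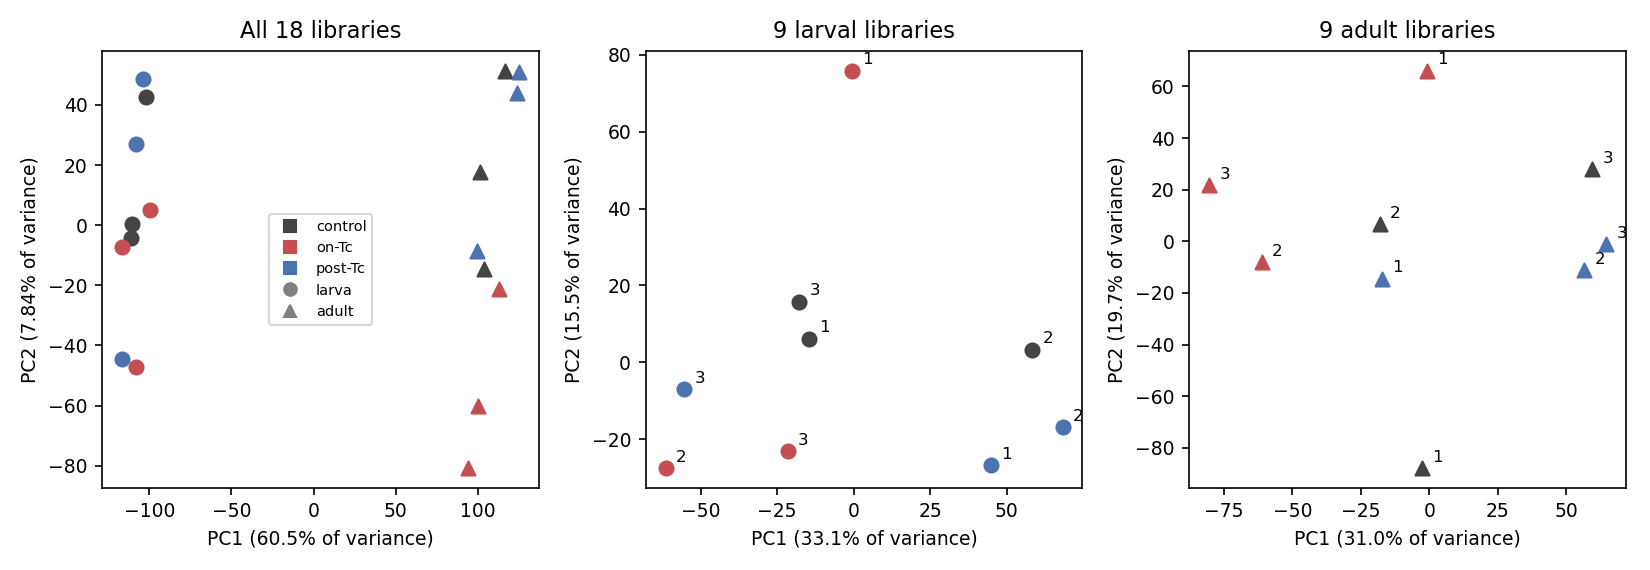
Principal components of log2 CPM for all 18 libraries, for the 9 larval and for the 9 adult libraries; each point is a library, coloured by treatment and shaped by stage, and the numbers in the within-stage panels are replicate numbers. PC1 (60.5% of variance) parts the stages in the left panel, the larval groups are mixed in the middle panel, and in the right panel on-Tc 2 and on-Tc 3 have the lowest PC1 values of the adult libraries.

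The comparison of untreated adults with untreated larvae describes how the midgut transcriptome of these production flies differs between the 2 stages. Of 12599 transcripts tested, 3456 differed by edgeR's quasi-likelihood test at an FDR of 0.05, with 1814 higher in adults and 1642 lower. The median fitted difference was 5.46-fold for those higher in adults and 3.89-fold for those lower (5.34-fold and 3.78-fold with the 75 and 58 transcripts that had 0 counts in the lower stage set at a floor of 3 counts per library). A total of 1593 transcripts were at least 2-fold higher and 1316 at least 2-fold lower. The change reached the bulk of the RNA. Transcripts higher in adults took 44.8% ± 5.27 (SD, n = 3) of adult control counts and 4.45% ± 0.402 (SD, n = 3) of larval control counts. Transcripts lower in adults took 45.9% ± 4.07 (SD, n = 3) of larval counts and 9.31% ± 0.507 (SD, n = 3) of adult counts. These shares describe transcripts selected on the same libraries. Of the 100 most abundant transcripts, 69 were called, 22 higher and 47 lower in adults, and the median difference over the 100 was 4.14-fold. The lists of the 100 most abundant transcripts in larval and in adult controls had 38 in common.

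The 2 largest rises and 2 largest falls between stages were near absent from the lower stage. In adult controls g9073.t1 stood at 88.2 ± 152 CPM (SD, n = 3), from 2 to 5923 counts per library, with 1 count in the 3 larval control libraries together; it passed edgeR's test (FDR 0.0204) but not limma-voom's (FDR 0.525). For g5024.t1 the adult control level was 16.4 ± 17.7 CPM (SD, n = 3) with 0 counts in larval controls, at least 346-fold higher against a floor of 3 counts per library, or 142-fold without adult control 1 (edgeR FDR 0.0091; limma-voom FDR 0.0739). In the other direction g6640.t1 had 13.6 ± 10.9 CPM (SD, n = 3) in larval controls and 0 counts in adult controls, at least 164-fold lower in adults, or 89.5-fold without larval control 3 (edgeR FDR 7.9e-04). The larval control level of g4280.t1 was 83.0 ± 58.5 CPM (SD, n = 3), with 2 counts in the adult controls together (edgeR FDR 1.1e-05). Limitation to a stage was rare by a strict rule over all 9 libraries of each stage, treated ones included. A level of at least 1 CPM in all 9 libraries of a stage with 0 counts throughout the other was found for 1 adult and 1 larval transcript, and allowing up to 3 counts per library gave 8 and 9. With a library left out, edgeR called 2374 to 3071 transcripts, and g9073.t1 lost its call in 4 of the 6 fits; its 5923 counts were in adult control 3, without which its fitted log2 difference fell from 13.44 to 5.98. DESeq2 called 4260 transcripts between stages and limma-voom 3555. All larval control libraries carried the same library-name digit and the adult controls carried both, so the digit partly went with stage. With the digit as a covariate edgeR called 2573 transcripts, 1385 higher and 1188 lower in adults.

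**Figure D2:**
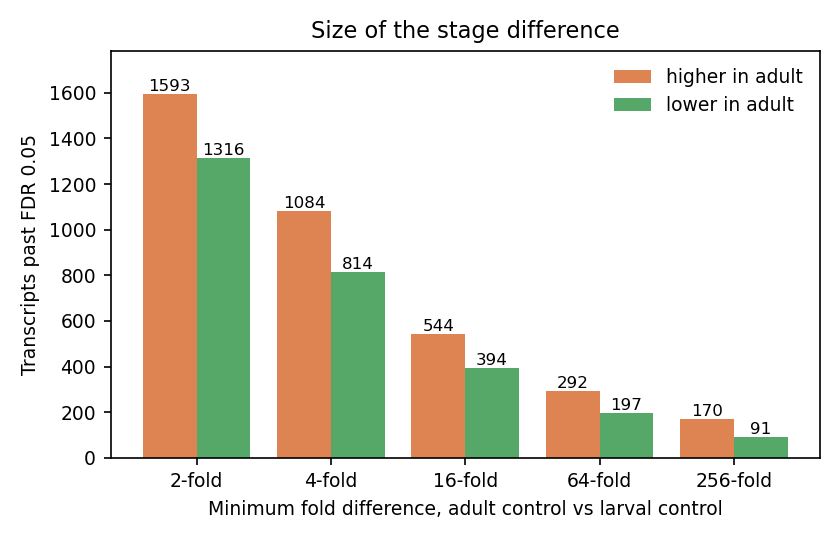
Number of transcripts past FDR 0.05 in adult against larval controls (edgeR, 3 libraries per group) by minimum fitted fold difference, with bars for those higher and those lower in adults. At 16-fold or more, 544 were higher and 394 lower in adults; the largest folds depend on low counts in the lower stage.

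In larval midguts no transcript passed the threshold in any treatment comparison. For on-Tc against control, edgeR called 0 of 11584 transcripts (smallest FDR 0.302), with 284 at an unadjusted p under 0.05, which is 2.45% of those tested; DESeq2 called 16 and limma-voom 0. For post-Tc against control, edgeR called 0 (smallest FDR 0.344; 276 at an unadjusted p under 0.05), DESeq2 5 and limma-voom 0. For post-Tc against on-Tc, edgeR called 0 (smallest FDR 0.422, with 617 at an unadjusted p under 0.05), DESeq2 22 and limma-voom 0. The unadjusted counts depended on single libraries. With a library left out they ranged, in the order above, from 221 to 472, from 199 to 667 and from 344 to 1793, while edgeR still called 0. Among the 100 most abundant larval transcripts the median fitted difference was 1.22-fold for on-Tc against control and 1.23-fold for post-Tc against control. The typical 95% interval of a larval fold change extended 1.95-fold to either side. In counts simulated with the larval spread, the test found 18.7% of transcripts changed 4-fold and 60% of those changed 8-fold, so changes of a few fold in single transcripts were often not detectable with 3 libraries per group.

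In adult midguts some transcripts passed the threshold during tetracycline, in a list that depended on single libraries. Of 11435 transcripts, 27 passed edgeR's test for on-Tc against control, 6 higher and 21 lower. The higher ones rose 2.75-fold to 41.2-fold (median 6.75) and the lower ones fell 2.52-fold to 4.79-fold (median 3.20). The largest rise was that of g17104.t1, from 0.831 ± 0.267 CPM (SD, n = 3) in controls to 34.1 ± 29.6 CPM (SD, n = 3) on tetracycline, a log2 change of 5.36 ± 0.78 (SE; edgeR FDR 0.0437). The level of g11224.t1 rose by 4.92 ± 0.71 (log2, SE), from 0.154 ± 0.0861 to 4.84 ± 3.85 CPM (SD, n = 3) (edgeR FDR 0.0437). The transcript g3349.t1 fell by 2.26 on the log2 scale (SE 0.26), from 4.49 ± 0.693 to 0.930 ± 0.200 CPM (SD, n = 3; edgeR FDR 0.0286). A similar fall, by 2.25 on the log2 scale (SE 0.25; edgeR FDR 0.0251), was measured for g17163.t1, from 5.36 ± 1.30 to 1.13 ± 0.0497 CPM (SD, n = 3). In these 4 transcripts all 3 on-Tc libraries lay beyond all 3 controls. None of the 100 most abundant transcripts was called, and their median fitted difference was 1.47-fold. For post-Tc against control in adults it was also 1.47-fold, so this size is not particular to on-Tc. Beneath the threshold, 2419 transcripts (21.2%) had an unadjusted p under 0.05, nearly balanced at 1112 higher and 1307 lower, and the groups did not overlap in 24.6% of transcripts, where chance gives 10%. DESeq2 called 1141 transcripts (524 higher, 617 lower), and up to 390 in other splits of the same libraries. In simulated counts with 200 changed transcripts 37.1% of its calls were false. That share depends on how many transcripts change, so it does not give the false share of the 1141. Limma-voom called 23, 20 of them among the 27, without g17104.t1 (FDR 0.0795) and g11224.t1 (FDR 0.0915).

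The on-Tc adult libraries also detected fewer transcripts at equal totals, 13157 ± 395 (SD, n = 3) against 14140 ± 76.7 (SD, n = 3) in controls and 13737 ± 285 (SD, n = 3) post-Tc; on-Tc libraries were 781 below the mean of the other 6 adult libraries (exact permutation test, two-sided, 84 splits, p = 0.0238). The count of 27 depended on single libraries. It was 0 without control 1, control 3, on-Tc 1 or on-Tc 3, 10 without control 2 (1 higher, 9 lower; 7 among the 27) and 21 without on-Tc 2. Those 21 were a largely different list with the opposite balance, 19 higher and 2 lower, and 6 were among the 27. It was also 0 with library totals in place of TMM factors (1982 at an unadjusted p under 0.05), with the library-name digit as a covariate (2208) and with only the 6 libraries compared (1946). With all 18 libraries it was 29 with the opposite balance, 21 higher and 8 lower, and 7 among the 27; without a filter on low counts it was 12, 6 higher and 6 lower. Without on-Tc 3, the library with the highest levels of both, the log2 rise was 4.41 for g17104.t1 and 4.09 for g11224.t1. The 4 named transcripts kept their direction in every fit with a library left out, but each stayed past FDR 0.05 in at most 1 of the 6 such fits.

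After tetracycline was withdrawn, some adult transcripts passed edgeR's test against the on-Tc adults and none against the controls. Post-Tc against on-Tc, 50 transcripts passed edgeR's test, 43 higher post-Tc (median 3.08-fold) and 7 lower (median 2.56-fold), while 2460 (21.5%) had an unadjusted p under 0.05, balanced at 1262 higher and 1198 lower. The level of g3164.t1 was higher by 3.39 ± 0.52 (log2, SE), at 8.86 ± 2.14 CPM (SD, n = 3) post-Tc, 0.846 ± 0.112 on-Tc and 3.41 ± 2.50 in controls (edgeR FDR 0.0456). That of g13828.t1 was higher by 2.55 ± 0.37 (log2, SE), at 5.06 ± 0.683 CPM (SD, n = 3) post-Tc, 0.870 ± 0.289 on-Tc and 2.32 ± 0.843 in controls (edgeR FDR 0.0448). The transcript g9527.t1 fell by 3.12 on the log2 scale (SE 0.33), from 8.59 ± 2.33 CPM (SD, n = 3) on-Tc to 0.984 ± 0.237 post-Tc, with 1.37 ± 0.302 in controls (edgeR FDR 0.0447). An abundant transcript, g4404.t1, fell by 2.32 on the log2 scale (SE 0.31), from 946 ± 233 CPM (SD, n = 3) on-Tc to 189 ± 37.9 post-Tc, with 129.6 ± 35.4 in controls (edgeR FDR 0.0447). DESeq2 called 1304 (597 higher, 707 lower) and limma-voom 59, 45 of them among the 50, without g3164.t1 (FDR 0.0557). The count was 0 with only the 6 libraries compared (2637 at an unadjusted p under 0.05) and 2 with library totals alone, the library-name digit as a covariate or no filter on low counts. With all 18 libraries it was 16, 4 higher and 12 lower. It was 13 without on-Tc 2 (3 higher and 10 lower, the opposite balance, with 3 among the 50), 1 without post-Tc 3, and 0 without on-Tc 1, on-Tc 3, post-Tc 1 or post-Tc 2.

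**Figure D3:**
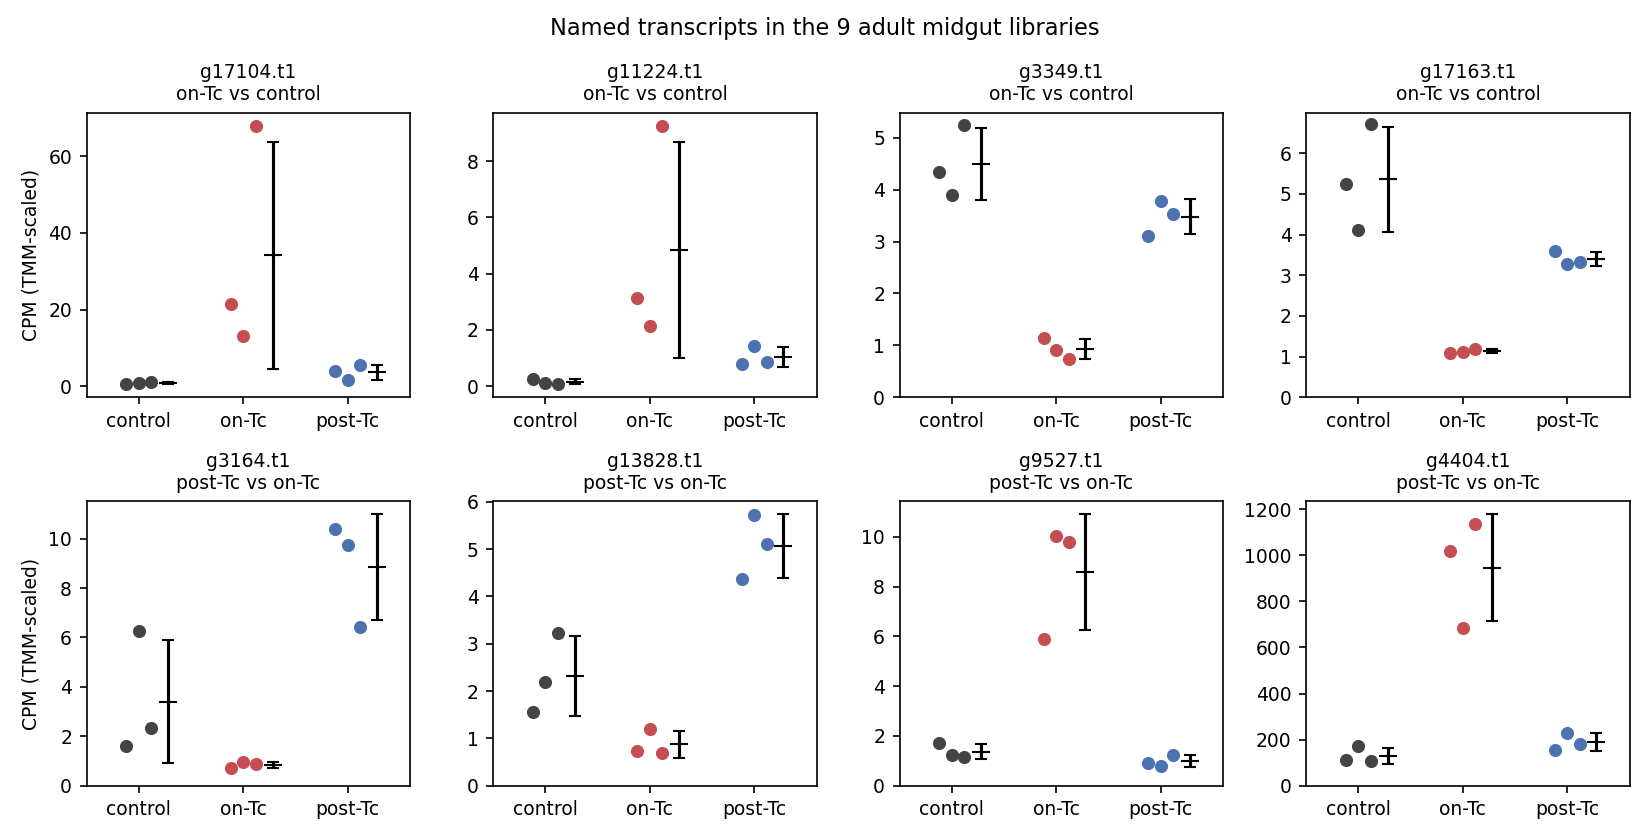
CPM (TMM-scaled) in each of the 9 adult libraries for the 4 transcripts named for on-Tc against control (top) and the 4 named for post-Tc against on-Tc (bottom); points are libraries, and bars give the mean and SD of 3. The on-Tc libraries lie apart from both other groups in all 8 panels, for example at 686 to 1134 CPM for g4404.t1.

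For post-Tc against control, the comparison that bears on lasting effects, edgeR called 0 of 11435 adult transcripts (smallest FDR 0.597), with 750 (6.56%) at an unadjusted p under 0.05; DESeq2 called 83 and limma-voom 0. The groups did not overlap in 11.7% of transcripts, where chance gives 10%. Controls were taken before tetracycline and post-Tc animals after it, so time of collection cannot be told apart from treatment here either. A typical 95% interval extended 1.75-fold to either side. Such an interval does not mean that 2-fold changes would have been called. In counts simulated for on-Tc against control in adults, edgeR's test found 0% of transcripts changed 2-fold and a minority of those changed 4-fold. It found 62% of those changed 8-fold. Recovery was not simulated for post-Tc against control, so lasting changes of a few fold in single transcripts may have been missed. In the median, the 27 transcripts called on tetracycline lay near the control level post-Tc, but 20 of them were still on the on-Tc side of it. By direction, the median log2 difference of post-Tc from control was 0.698 for the 6 that had risen and -0.154 for the 21 that had fallen. The median of the post-Tc change divided by the on-Tc change was 0.141, and 25 of the 27 lay closer to control than to on-Tc. The 4 named transcripts lay between the other groups post-Tc, at 3.68 ± 1.96 CPM (SD, n = 3) for g17104.t1, 1.03 ± 0.352 for g11224.t1, 3.48 ± 0.338 for g3349.t1 and 3.39 ± 0.176 for g17163.t1. In all 4 the post-Tc libraries did not overlap the controls, though none passed edgeR's test for post-Tc against control. Of the 27, 18 were also called post-Tc against on-Tc, all 18 in the opposite direction. These comparisons share the on-Tc libraries, and lists of the same lengths from simulated groups without effects shared 6.4 on average and 10 at most (independent lists would share 0.0826 in opposite directions). Each transcript was simulated independently, without the library differences that real transcripts share. The values from simulated groups without effects in this paragraph may therefore vary too little to judge chance. Shared controls also link the on-Tc and post-Tc changes across transcripts. Their correlation was 0.378 in adults, where simulated unchanged groups gave 0.488, and 0.274 in larvae (simulated 0.491). The covariance was 0.279 in adults (simulated 0.219) and 0.119 in larvae (simulated 0.203). The 3 control libraries were not split, since 1 part would have kept a single library.

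Because the control and post-Tc adults were close, the on-Tc adults were also compared with both groups pooled as 6 libraries, a grouping chosen after the data were seen. In that comparison 450 of 11435 transcripts passed edgeR's test, 242 higher on tetracycline (median 2.20-fold) and 208 lower (median 2.78-fold). Their groups did not overlap for 435 of the 450, and for 14.6% of all transcripts tested, where chance gives 2.38%. DESeq2 called 1632 and limma-voom 274. The count was 96 with library totals alone (42 higher, 54 lower), 212 with the library-name digit as a covariate and 257 without a filter on low counts. The 450 included 25 of the 27 and 46 of the 50 transcripts above. The 242 took 6.32% ± 1.55 (SD, n = 3) of counts on-Tc, 2.29% ± 0.772 in controls and 1.96% ± 0.527 post-Tc. The 208 took 0.274% ± 0.0198 (SD, n = 3) on-Tc, 0.868% ± 0.0351 in controls and 0.748% ± 0.0871 post-Tc. Among them, chosen after their values were seen, g43.t1 rose by 8.09 ± 1.13 (log2, SE), from 0.0360 ± 0.0568 CPM (SD, n = 6) to 11.9 ± 11.9 CPM (SD, n = 3) on-Tc (edgeR FDR 0.0151), and by 7.08 without on-Tc 3 (edgeR FDR 0.0593). The abundant transcript g10961.t1 fell by 4.69 on the log2 scale (SE 1.07), from 1671 ± 1423 CPM (SD, n = 6) to 64.9 ± 60.1 CPM (SD, n = 3) on-Tc (edgeR FDR 0.0460), but it did not pass with any library left out. The count fell to 59 without on-Tc 1, 242 without on-Tc 2, 4 without on-Tc 3, 147 without control 3, and it lay between 117 and 158 without post-Tc 1, post-Tc 2 or post-Tc 3. The same comparison in larvae gave 0 of 11584 by edgeR (529 at an unadjusted p under 0.05), 21 by DESeq2 and 0 by limma-voom.

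**Figure D4:**
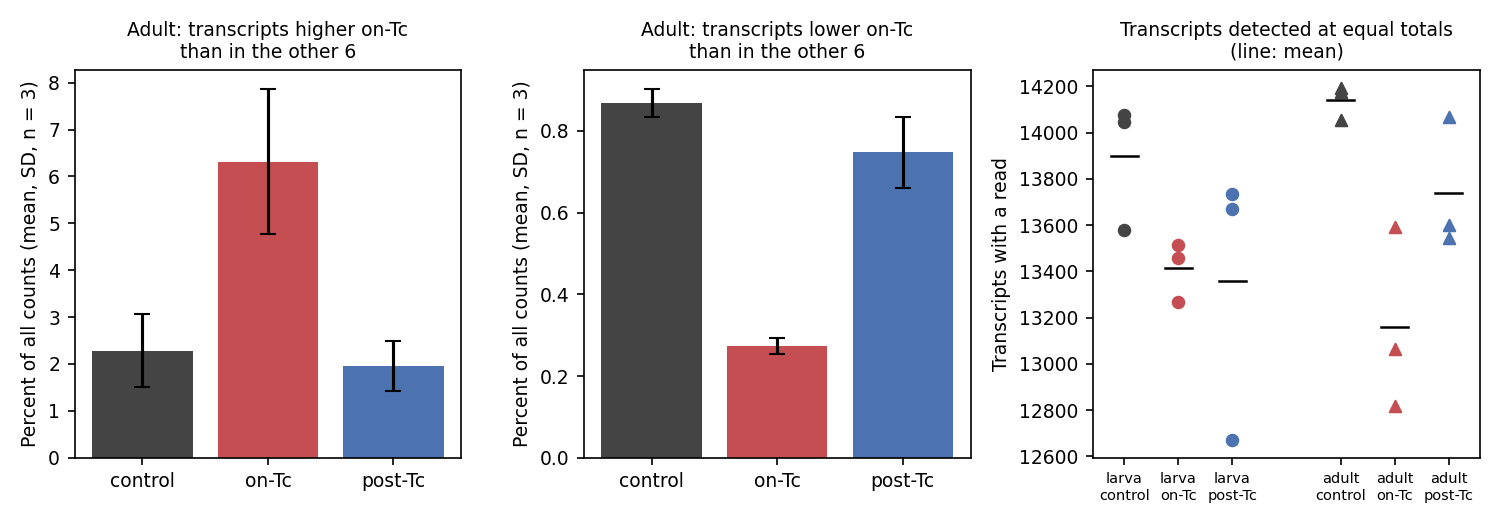
Share of all counts taken in adult midguts by the 242 transcripts higher and the 208 lower on-Tc than in the other 6 libraries (bars: mean and SD of 3 libraries), and the number of transcripts with a read when each library is thinned to the smallest total (points: libraries; lines: means). The shares on-Tc are 6.32% and 0.274%; the transcripts were selected on these libraries, so the bars describe their abundance and are not a test.

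**Figure D5:**
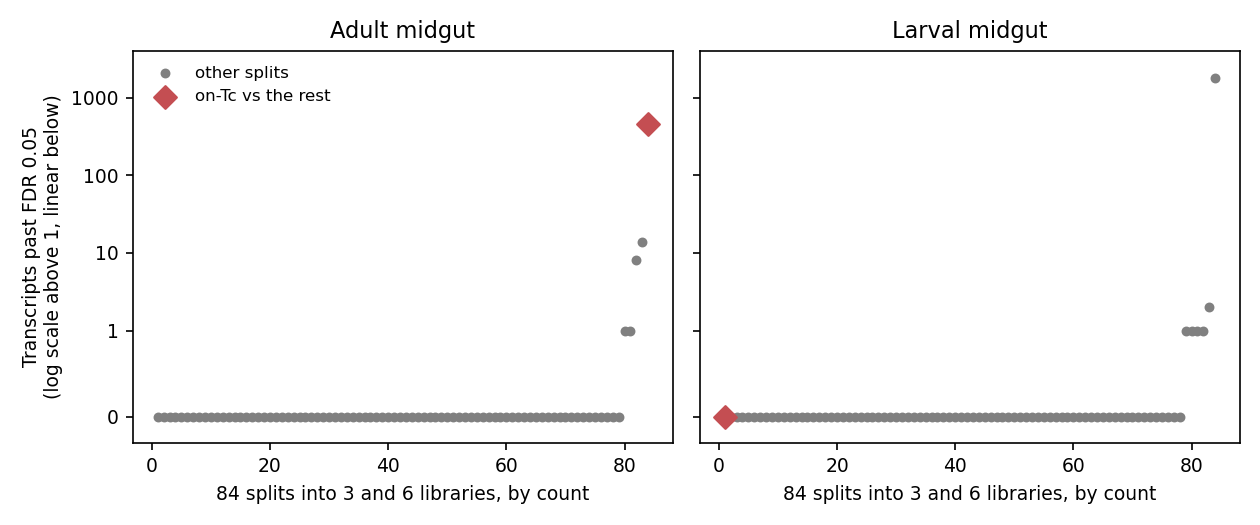
Number of transcripts past FDR 0.05 (edgeR) for each of the 84 ways to set 3 of the 9 libraries of a stage against the other 6, sorted by count, on an axis that is logarithmic above 1 and linear below. The on-Tc adults gave 450 and the highest other adult split 14, while the on-Tc larvae gave 0 and another larval split 1766. At an unadjusted p under 0.05 (edgeR, not drawn) the gap was much smaller, with 2811 for the on-Tc adults and 2459 for the highest other adult split.

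Whether larvae and adults responded differently was tested as an interaction over all 18 libraries. For the on-Tc effect, edgeR called 0 of 12599 transcripts (smallest FDR 0.0906), with 903 (7.17%) at an unadjusted p under 0.05; DESeq2 called 52 and limma-voom 0. For the post-Tc effect, edgeR called 0 (smallest FDR 0.842; 655 at an unadjusted p under 0.05), DESeq2 6 and limma-voom 0. A difference between the stages in their response was therefore not detected. Of the 27 transcripts called in adults, 23 had the same sign of change in on-Tc larvae by edgeR's fit (22 by mean log2 CPM, where another of the 10 larval splits gave 24 of 1 sign), 1 of them with an unadjusted larval p under 0.05, and 13 had an unadjusted interaction p under 0.05. The 27 were selected on the adult on-Tc change, which is itself part of the interaction, so the 13 are not a test of a difference between stages. The typical 95% interval of an interaction extended 2.57-fold to either side.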

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

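The alternatives added after the data were seen were halved counts, transcripts summed per gene number, the larval axis as a covariate, and every value for on-Tc against the other 6 libraries and for the correlation of larval with adult changes. The counts of 0 in larvae and for post-Tc against control in adults, and the stage count, stayed at 0 or within 1.5 times under every alternative run except DESeq2 for the counts of 0. The gene list tests were not run, because no names are paired with the IDs. Unless stated, the cause was not tested.

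With DESeq2, larval counts rose from 0 to 16 (on-Tc against control), 5 (post-Tc against control), 22 (post-Tc against on-Tc) and 21 (on-Tc against the other 6). Adult counts became 1141 (on-Tc against control, from 27), 83 (post-Tc against control, from 0), 1304 (post-Tc against on-Tc, from 50) and 1632 (on-Tc against the other 6, from 450). Interaction counts became 52 (on-Tc) and 6 (post-Tc), from 0. For on-Tc against control in adults, 37.1% of DESeq2's calls were false in simulated counts with 200 changed transcripts, a share that does not carry over to the 1141. With limma-voom the adult on-Tc against other 6 count was 274.

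For adult on-Tc against control, post-Tc against on-Tc and on-Tc against the other 6, in that order, the counts were 0, 2 and 96 with library totals alone, 12, 2 and 257 without a filter on low counts, and 0, 2 and 212 with the library-name digit as covariate. With a filter of 1 CPM in 3 libraries the first 2 were 45 and 81, with only the 6 libraries compared 0 and 0, and with the larval axis as covariate 0 and 0. With all 18 libraries, post-Tc against on-Tc gave 16 (4 shared, 25% higher against 86.0%), and on-Tc against control 29 (7 shared, 72.4% higher against 22.2%). Library totals alone moved the median log2 change of all transcripts to -0.15 and -0.19 in larvae (post-Tc against control and against on-Tc), -0.14 in adults (post-Tc against control) and -0.11 (on-Tc interaction).

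Replicate numbers did not pair the libraries: same-numbered libraries' deviations correlated from -0.390 to 0.354 in larvae and from -0.382 to 0.262 in adults, and 1 library per stage correlated best with its own number. With the replicate block the counts were 0 (adult on-Tc against control), 0 (post-Tc against on-Tc) and 18 (on-Tc against the other 6; 2 higher, 16 lower); it changed no other count by over 1.5 times.

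With a library left out, the counts ranged from 0 to 21 for adult on-Tc against control, 0 to 13 for post-Tc against on-Tc (both highest without on-Tc 2, where the balance reversed to 19 higher and 2 lower with 6 shared, and to 3 higher and 10 lower with 3 shared), 4 (without on-Tc 3) to 555 (without control 2) for on-Tc against the other 6, and 0 to 1 (without adult control 1) for the on-Tc interaction. Such fits have fewer libraries. Of 120 values of the named transcripts under alternatives, 58 stayed past the threshold and 62 fell short, 47 of these with a library left out and 9 with the block; none changed direction.

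The larva-adult correlation of on-Tc changes, 0.254, was 0.2997 among transcripts of at least 10 CPM in both stages (p = 0.07 over 100 pairs of splits, exact), 0.0416 with transcripts per read removed (exact p = 0.4), and 0.140 (without larval on-Tc 2) to 0.271 (without larval on-Tc 1) with a library left out. Depth limits transcripts near the floor of 3 counts per library.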

Other observations

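The ratio of post-Tc to on-Tc changes and the splits of the larva-adult correlation were tests chosen only after their results were seen; on-Tc against the other 6 libraries, the larva-adult correlation itself, and the neighbour, axis and thinning tests were added after the data were seen.

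Transcripts with neighbouring gene numbers changed together between the stages. Among 9120 pairs of consecutive tested gene numbers, 705 pairs were both called in the same direction, against a mean of 347 and a maximum of 411 in 10000 permutations, and 236 in opposite directions. The longest run, chosen after its values were seen, was 9 transcripts higher in adults from g3536.t1 to g3544.t1 (fitted log2 changes 7.59 to 11.21). Duplicated or co-regulated neighbours are a candidate explanation, but single genes split into several models, or reads shared by near-identical copies, would give the same, and coordinates were not used here.

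The transcripts that fell in on-Tc adults leaned to the adult stage. Of the 208 lower on-Tc than in the other 6 libraries, 91 were higher in control adults than control larvae and 13 lower. Of the 242 that rose, 20 were higher in adults and 36 lower, and of all 11435 tested, 1798 and 1344. The same adult controls enter both comparisons, so the lean was not tested.

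The first pattern weighed is the change in on-Tc adults, for which, with 10 splits of 3 against 3, a share under 0.05 cannot be reached: for on-Tc against control the real split gave 27 and the highest other 0 (DESeq2 1141 and 390), and for post-Tc against on-Tc 50 and 0. For on-Tc against the other 6, 1 of 84 splits gave as many as 450 (highest other 14), the smallest share possible. The grouping was chosen because on-Tc had already stood apart, so this restates that observation and chance stays open. At an unadjusted p under 0.05 (edgeR) on-Tc gave 2811, but the split of control 1, post-Tc 2 and post-Tc 3 gave 2459. The count of 450 fell to 4 without on-Tc 3 and 59 without on-Tc 1. Thinned libraries kept 100.4% of the calls' median change (bootstrap 95% interval 96.5% to 111.9%). This cannot decide on unequal depth, because random thinning leaves each transcript's expected share of counts unchanged. At equal totals 33 transcripts were called, 25 of them among the 27. An axis found in the larvae cannot be told apart from the treatment, since all 3 on-Tc adults scored below the other 6 (1 of 84 splits as large, exact p = 0.0119); with it as a covariate 89.4% of the change was left (78.7% to 103.4%, over transcripts), but no call was, as the median SE rose from 0.24 to 0.42, and a covariate that separates the groups decides nothing. The rearing treatment may explain the change in on-Tc adults, but the values cannot decide it. The median ratio of post-Tc to on-Tc change was 0.141, below the 0.376 to 0.609 of 10 simulations without effects. Those simulations lacked library differences shared by many transcripts, so their range may be too narrow to judge chance. Anything that set the on-Tc adults alone apart would also give a low ratio. A batch, cage or day that went with the on-Tc adults stays open, as the labels name none. Midguts were taken before, during and after tetracycline, so time of collection cannot be told apart from treatment.

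The second pattern is a correlation of larval with adult on-Tc changes across 12599 transcripts, which are not independent replicates (r = 0.254). Only 1 of 100 pairs of splits was as large (exact p = 0.01, the smallest they can give; highest other 0.219), but this is the smallest p of 3 contrasts, with 0.125 for on-Tc against post-Tc (exact p = 0.22; highest other 0.298) and 0.0396 for post-Tc against control (exact p = 0.69), so chance stays open. Among transcripts of at least 10 CPM r was 0.2997, but there 7 of 100 pairs were as large (exact p = 0.07, highest other 0.339). Since other splits also gave larger values in that subset, this cannot decide on low-count transcripts as the source. Removing the number of transcripts detected at equal totals left 0.0416, but that number separates control from on-Tc in both stages, so a treatment effect and lower library complexity cannot be told apart. The 27 adult calls moved the same way in larvae by 0.46 on average (log2), as large in 3 of 10 splits (highest other 0.60).

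The third pattern is an axis of library differences in larvae, holding 35.3% of larval variance within groups and 1.10% of adult. Over 18 libraries with stage means removed, no link with library depth was detected (r = 0.0925, permutation p = 0.681, rho = 0.0167, 0.268 without the 2 farthest). The 95% interval of this r, -0.391 to 0.536, is wide. In the 9 larval libraries r was 0.248 (permutation p = 0.512), or 0.631 without the 2 farthest, and in the 9 adult libraries -0.132. The axis may therefore still follow depth in larvae. It followed the number of transcripts detected at equal totals (r = 0.628, permutation p = 0.00145, adjusted over 3 measures 0.00218; rho = 0.658, permutation p = 0.00544; 0.5001 without the 2 farthest), and also the share of counts taken by the 10 most abundant transcripts (r = 0.5065, permutation p = 8.3e-04, adjusted 0.00218; rho = 0.742, permutation p = 0.00117; 0.532 without the 2 farthest). The 95% interval of the r of 0.628 was 0.228 to 0.847. Within stages this r was 0.701 in larvae and 0.752 in adults (permutation p adjusted over 3 measures 0.0429 and 0.0345, n = 9 each). The share of the 10 most abundant transcripts gave 0.736 and 0.753. Library complexity and another source cannot be told apart from these correlations. No biological explanation of the axis was tested.

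For the other comparisons of 3 against 3, 10 splits cannot give a share under 0.05: real and highest other counts were 0 and 0 (larval on-Tc against control), 0 and 772 (larval post-Tc against control), 0 and 0 (larval post-Tc against on-Tc), 0 and 3 (adult post-Tc against control) and 3456 and 0 (stage). For the interactions, 30 of 30 drawn splits gave as many as the real 0, with 5 (on-Tc) and 14 (post-Tc) the highest others, a count fixed by the 0; at an unadjusted p under 0.05, 6 and 10 of the 30 gave as many as the real 903 and 655. For 3 larvae against 6, the on-Tc larvae gave 0, so 84 of 84 splits gave as many by construction. The highest, control 2, post-Tc 1 and post-Tc 2 against the other 6, gave 1766; these are the libraries the first larval component sets apart, so the count restates that structure.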
